A study of Mus musculus with 4 samples.

How the data were processed

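Nuclei from 1 brain hemisphere each of 4 mice at postnatal day 12 were profiled with a droplet 3′ kit (10x Chromium, chemistry v3.1) and sequenced on an Illumina NovaSeq X Plus, per the labels' protocols. The authors deposited 1 table of UMI counts per library, with 33696 features by symbol in rows and nucleus barcodes in columns, and per the submitters' processing notes the counts were made with Cell Ranger 9.0.0 and STAR on mm10. No value was below 0 and every value above 0 was whole, so the deposited counts were used as raw UMI counts. The labels number the libraries of each group as biological replicates 1 and 2, and do not say whether mice of like number were littermates. The tables held 9741, 19550, 12243 and 17509 barcodes for Ctrl 1, Ctrl 2, Cre 1 and Cre 2. The annotation release behind the symbols is not stated, and 248 features were named by an Ensembl identifier. Coordinates and gene spans were taken from GENCODE vM21 on GRCm38 (mm10), which matched 29478 of the 33696 features by symbol.

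Nuclei were kept with at least 500 UMIs, at least 300 genes, at most 5% mitochondrial UMIs and no doublet call by Scrublet, run on each library with an expected rate of 0.08 and its automatic threshold in scanpy 1.11.5. Scrublet set thresholds of 0.128, 0.157, 0.123 and 0.259 and called 21.3%, 16.8%, 18.8% and 4.90% of the nuclei of Ctrl 1, Ctrl 2, Cre 1 and Cre 2 as doublets, so the share removed differed between libraries. Kept nuclei were log-normalised and clustered on 3000 variable genes, 40 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2) without batch integration. A cluster was named by 1 of the marker lists when at least 3 markers had a z score of at least 1 over clusters and were seen in at least 10% of its nuclei, and when the best class led the next by a factor of at least 1.2. It stayed unnamed where its leading 10 genes went against the name. The margin and the limits on markers were set once the clusters had been seen. A cluster's class is written as astrocyte-like and so on, since the name rests on transcripts alone. Library shares carry exact binomial 95% intervals, and intervals and floors (3 counts) cover counting error only.

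UMIs were summed per library over all kept nuclei and over each class with at least 50 nuclei in every library. The 2 Ctrl and the 2 Cre libraries were compared with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F-test with a robust fit, R 4.3.3), with Benjamini-Hochberg adjustment within each sum and calls at an adjusted p under 0.05. Nuclei per class were compared with the same model and with an exact two-sided permutation test. Lists of genes, 32 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), for lists with at least 5 tested genes, with adjustment over the lists of a sum. Genotype effects in astrocyte-like and excitatory neuron-like nuclei were compared by an interaction term in edgeR. The Severe and Mild libraries were compared as log2 ratios, and genes were counted and named at a mean of at least 20 CPM. List medians had no such limit and were set against 10000 random lists of like size and expression. All tests were two-sided.

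The sample groups, the nucleus filters, the markers, the 32 lists, the tests, the named-gene rule and most alternatives were set before the data were examined. Genes were named by rule as the 10 highest and 10 lowest folds among called genes in pooled and astrocyte-like nuclei, 3 each way in other classes, up to 4 members with the lowest p of each discussed list, and for Severe against Mild the 5 highest and 5 lowest ratios above 2 times the ratio between the Ctrl libraries. Since edgeR called 0 genes, the first parts of that rule named none. Alternatives tried were DESeq2 1.42.0, RLE factors, no filter on low counts, thinning of each sum to the smallest library total, doublets kept, at least 1000 UMIs per nucleus, Leiden resolution 0.5, the replicate number as a block, each library left out in turn, an estimated correlation and fry for lists, and equal class shares for Severe against Mild. Added later were 1 doublet limit of 0.25 for all libraries, shares outside the cerebellar and cycling classes, pooled nuclei of the 10 classes alone, and removal of the trend of the list test on gene span.

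The pipeline was tested on simulated data with the dispersion of each fit. Of 100 genes changed 4-fold it called 23 in pooled, 36 in excitatory neuron-like, 59 in interneuron-like, 45 in subcortical neuron-like, 16 in astrocyte-like, 40 in precursor-like, 3 in oligodendrocyte-like, 0 in microglia-like, 0 in endothelial-like, 1 in mural-like and 17 in fibroblast-like nuclei. Of 100 genes changed 2-fold it called 0 to 4, so changes of that size in single genes were mostly missed at the fitted dispersion with 2 libraries per group. With Poisson noise alone it called 57 to 87 of them. At the fitted dispersion 0 to 6 unchanged genes were called in a sum. A list of 30 genes changed 2-fold was called in each of the 11 sums, and 0 unchanged lists were. Each gene was drawn independently, so members of a list did not vary together. The simulation therefore cannot show how often camera at its preset correlation calls unchanged lists of correlated genes.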

Results

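RNA from single nuclei was sequenced from 1 brain hemisphere per mouse at postnatal day 12, in 4 libraries. The 2 libraries of the Ctrl group came from mice with 1 floxed and 1 null copy of Hpdl. The 2 libraries of the Cre group came from mice of the same Hpdl genotype that also carried Nestin-cre, a recombinase expressed in the neural precursors that give rise to neurons, astrocytes and oligodendrocytes. Hpdl encodes a mitochondrial enzyme, a relative of the tyrosine-degrading enzyme encoded by Hpd, that makes 4-hydroxymandelate for the head group of coenzyme Q, the electron carrier of the respiratory chain. The series title names a neurometabolic disease related to this gene, and the comparison of the groups asks what its loss from neural cells does to each kind of brain cell. The labels describe the first Cre mouse as Mild and the second as Severe, so the Cre group holds 1 mouse of each phenotype. After filtering, Ctrl 1 held 7664 nuclei and 62255127 UMIs, Ctrl 2 held 16270 nuclei and 85943973 UMIs, Cre 1 (Mild) held 9930 nuclei and 49403547 UMIs, and Cre 2 (Severe) held 16634 nuclei and 105199191 UMIs. The median nucleus held 6243 UMIs in Ctrl 1, 4017 in Ctrl 2, 3350 in Cre 1 and 4207 in Cre 2. Mitochondrial transcripts made up a median of 0.109%, 0.0889%, 0.0845% and 0.167% of the UMIs of a nucleus in the same order.

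Hpdl itself could not be used to check the deletion. Ctrl 1 held 0 Hpdl UMIs, Ctrl 2 held 1, Cre 1 held 1 and Cre 2 held 2, which is 0, 0.0116, 0.0202 and 0.0190 CPM, the usual unit of counts scaled to the UMIs of a library. CPM in the comparisons below also carry the TMM factors. Exceptions are ratios with counting intervals, sums over regional code genes and values with equal class shares. The exact 95% Poisson upper limits were 0.0593, 0.0648, 0.113 and 0.0687 CPM, and 3 counts in a library correspond to 0.0482, 0.0349, 0.0607 and 0.0285 CPM. Both groups lay at or under that floor, so no fold is given and no difference was detectable at this depth. The gene lies on chromosome 4, from 116819904 to 116821707 on the minus strand of GRCm38, and its annotation holds 1 exon with the coding sequence from 116820150 to 116821262. The labels do not say which part is floxed, and a 3′ tag from a part that stays in place would check nothing.

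Clustering gave 42 clusters, of which 34 took the name of 1 of 16 classes by marker genes and 8 stayed unnamed. The Severe library differed most in its makeup. Cerebellar granule neuron-like nuclei made up 37.4% of Cre 2 (6213 nuclei), against 0.222% of Cre 1 (22 nuclei), 0.0261% of Ctrl 1 (2 nuclei) and 0.00615% of Ctrl 2 (1 nucleus). Purkinje neuron-like nuclei made up 0.625% of Cre 2 and 0.0101% of Cre 1. Immature or cycling neural cell-like nuclei made up 4.98% of Cre 2 and 0.0201% of Cre 1. No Ctrl nucleus lay in either of these 2 classes, where a count of 0 allows a share of up to 0.0481% in Ctrl 1 and 0.0227% in Ctrl 2 (exact 95% limit). At Leiden resolution 0.5, however, the cycling class held 0.431% and 0.430% of Ctrl, 0.161% of Cre 1 and 5.42% of Cre 2, and the granule class 18.7% of Cre 2. An unnamed cluster with Top2a, Knl1 and Kif11 among its leading genes held 36 and 119 Ctrl nuclei, 14 of Cre 1 and 80 of Cre 2 at resolution 1. Subcortical glutamatergic neuron-like nuclei made up 1.12% and 4.86% of the Ctrl libraries, 1.47% of Cre 1 and 11.5% of Cre 2. Of those of Cre 2, 1890 lay in a cluster with Ebf2, Baiap3 and B230217J21Rik among its leading genes. The same genes were among those of an unnamed cluster with 15.1% and 10.3% of Ctrl, 6.445% of Cre 1 and 0.186% of Cre 2. The shares of this class thus depend on which of these clusters took its name. Telencephalic excitatory neuron-like nuclei made up 21.4% and 31.2% of the Ctrl libraries, 19.0% of Cre 1 and 8.44% of Cre 2. Medium spiny neuron-like nuclei, the main neurons of the striatum, varied within both groups, with 12.1% and 1.30% in Ctrl and 14.5% and 0.186% in Cre. Of the 16 classes, edgeR called 0 between the groups, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.581. An exact two-sided permutation test of 2 against 2 libraries cannot go below 0.333.

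In 5 of the 16 classes both Cre libraries lay below both Ctrl libraries, namely oligodendrocyte-like, inhibitory interneuron-like, excitatory neuron-like, endothelial cell-like and mural cell-like nuclei. In 3 classes, granule-, Purkinje- and cycling neural-like, both lay above, and chance alone gives 16.7% of classes each way. At resolution 0.5 neither held for cycling neural-like nuclei, where Cre 1 lay below both Ctrl libraries, or for mural cell-like nuclei, where Cre 1 at 0.826% lay between them (0.770% and 0.885%). Oligodendrocyte-like nuclei made up 2.53% and 3.77% of the Ctrl libraries, 1.46% of Cre 1 and 1.19% of Cre 2, and interneuron-like nuclei 4.97%, 6.42%, 3.27% and 1.94% in the same order. Among nuclei outside the granule-, Purkinje- and cycling neural-like classes, the Cre 2 shares were 2.09% for oligodendrocyte-like, 3.40% for inhibitory interneuron-like, 14.8% for excitatory neuron-like and 1.21% for endothelial cell-like nuclei, still below both Ctrl libraries, whereas mural cell-like nuclei at 0.959% lay above both (0.653% and 0.762%). That base kept unnamed clusters that held 7.79% and 6.32% of all Cre 2 nuclei and at most 0.0261% of a Ctrl library. It also kept a subcortical neuron-like cluster with 1890 nuclei of Cre 2 and 12 and 2 of Ctrl. Such nuclei lower the other shares of Cre 2, so this comparison cannot tell fewer nuclei of a class from more of other kinds. Astrocyte-like nuclei made up 8.73% and 12.3% in Ctrl, 13.8% in Cre 1 and 8.15% in Cre 2. Oligodendrocyte precursor-like nuclei made up 5.77% and 6.16% in Ctrl, 7.32% in Cre 1 and 3.66% in Cre 2, and microglia or macrophage-like nuclei 4.45%, 5.46%, 5.27% and 1.68% in the same order. Unnamed clusters held 30.8%, 21.4%, 24.7% and 16.6% of the nuclei of Ctrl 1, Ctrl 2, Cre 1 and Cre 2. An unnamed cluster led by Enpp6, Bcas1 and Bmp4, genes of oligodendrocytes about to form myelin, held 3.42%, 3.75%, 3.73% and 1.08%.

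**Figure D1:**
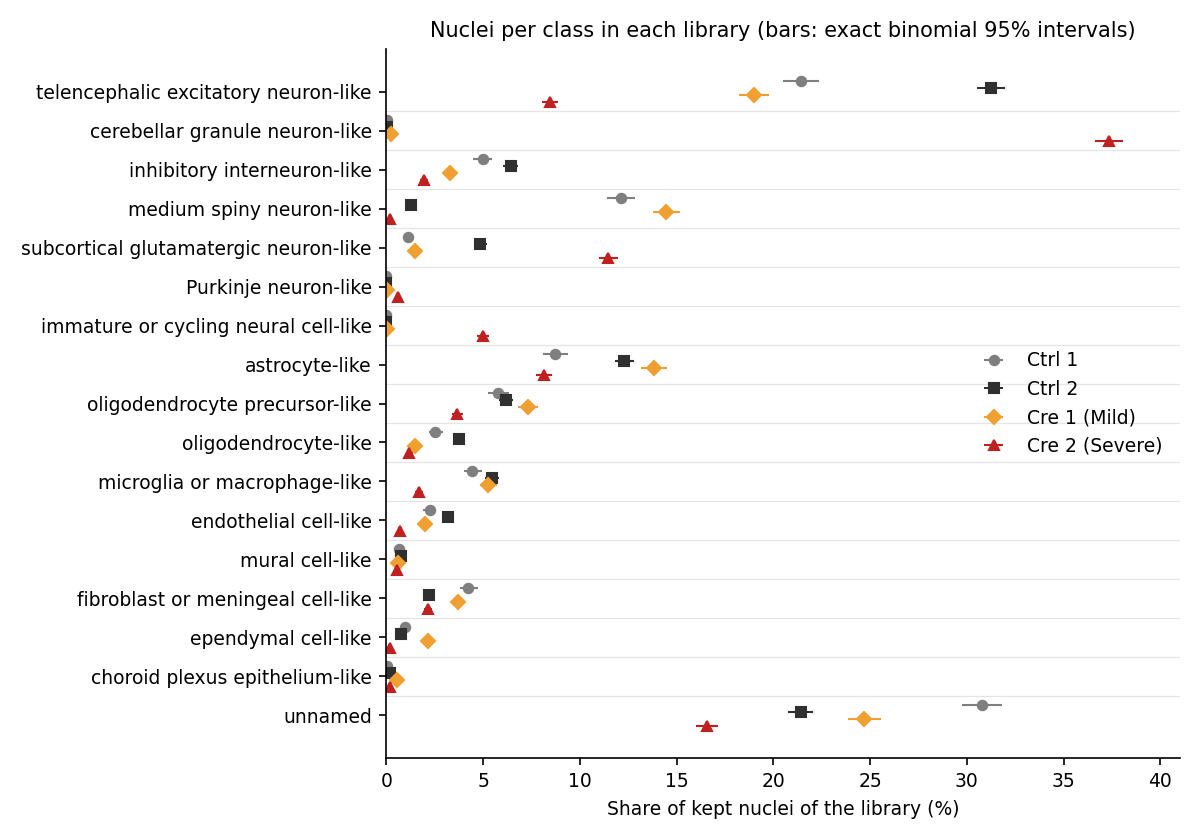
Share of the kept nuclei of each library (horizontal axis, percent) in each class (vertical axis), with exact binomial 95% intervals that cover counting error only. Cerebellar granule neuron-like nuclei lie at 37.4% in Cre 2 and at no more than 0.222% in the other libraries.

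For gene expression, UMIs were summed per library over all kept nuclei and over each of 10 classes with at least 50 nuclei in every library, with n = 2 libraries per group in every comparison. At the level of single genes edgeR called 0 genes in pooled nuclei and 0 in each of the 10 classes. At an unadjusted p under 0.05 there were 1245 of 23002 genes in pooled nuclei, 1324 of 18632 in telencephalic excitatory neuron-like, 1134 of 13537 in inhibitory interneuron-like, 1237 of 13429 in subcortical glutamatergic neuron-like and 754 of 14572 in astrocyte-like nuclei. The other classes gave 862 of 12008 in oligodendrocyte precursor-like, 449 of 10472 in oligodendrocyte-like, 435 of 10099 in microglia or macrophage-like, 265 of 6939 in endothelial cell-like, 182 of 3590 in mural cell-like and 607 of 10243 in fibroblast or meningeal cell-like nuclei. DESeq2 called 43 genes in pooled nuclei, 130 in excitatory neuron-like, 33 in interneuron-like, 26 in subcortical neuron-like, 97 in astrocyte-like, 31 in precursor-like, 14 in oligodendrocyte-like, 19 in microglia-like, 0 in endothelial-like, 1 in mural-like and 0 in fibroblast-like nuclei. Genes with both Cre libraries above both Ctrl libraries numbered 2642 in astrocyte-like nuclei, and 2646 had both below, where chance gives 2429 each way. In pooled nuclei these counts were 4248 and 4302, where chance gives 3834 each way. The median gene sat 0.11 log2 units higher in Cre in pooled and in excitatory neuron-like nuclei, and 0.10 in subcortical neuron-like nuclei, so folds of that size carry no direction of their own. With DESeq2-style size factors these medians were 0.09, 0.08 and 0.05 for the same sums. Leaving out single libraries changed the edgeR counts, to 2554 in pooled and 2047 in excitatory neuron-like nuclei without Cre replicate 1 and to 7 and 19 without Cre replicate 2. For lists of genes the calls given here are those of camera at its preset correlation, and with an estimated correlation it called 0 lists in each of the 11 sums.

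The clearest group of genes was that of reactive astrocytes, which astrocytes switch on after injury and in metabolic and neurodegenerative disease. In astrocyte-like nuclei all 25 tested members of the reactive astrocyte list were higher in Cre, with a median log2 fold of 1.97 and a camera adjusted p of 2.4e-18. The list was raised in both Cre mice, with a median of 2.48 in Mild and 1.85 in Severe against the Ctrl mean, while Ctrl 2 and Ctrl 1 differed by -0.27. Adjusted over the list alone 13 members were called, over all genes 0, and DESeq2 called 7. With 17 members the groups did not overlap with Cre higher, where chance gives 4.17. Without each library in turn the list stayed called, with adjusted p from 2.3e-19 to 7.8e-10, but not with an estimated correlation (adjusted p = 0.277) nor by fry for a shift one way (adjusted p = 0.138). Fry called it for change in either direction (adjusted p = 0.00601). Cd44, a receptor for hyaluronan that marks fibrous and reactive astrocytes, had a log2 fold of 3.04 (SE 0.37), from 5.59 and 6.77 CPM in Ctrl to 45.4 and 57.2 in Cre. Gfap, the intermediate filament that defines reactive astrocytes, had a log2 fold of 2.49 (SE 0.35), from 94.6 and 56.1 to 409 and 434 CPM.

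Cytokine-response genes were among the members. Osmr, the receptor subunit for oncostatin M, had a log2 fold of 2.36 (SE 0.43) in astrocyte-like nuclei, from 7.18 and 8.04 to 49.6 and 29.3 CPM. Serpina3n, a secreted protease inhibitor, went from 0 and 1 UMIs in Ctrl to 32 and 37 in Cre, a ratio of CPM of 51.0 with a counting interval of 8.85 to 2043. Astrocyte-like nuclei of Ctrl 1 and Cre 1 lay mostly in the same cluster (96.0% and 96.3%), whereas those of Ctrl 2 lay in another (99.3%) and those of Cre 2 in 2 further clusters (61.8% and 36.7%). The list members Gfap and Tnc were among the leading genes of the first cluster of Cre 2, and Tnc among those of the second. The Severe values of the list therefore also compare different clusters. The astrocyte-like nuclei of Cre 1 against those of Ctrl 1 alone gave a list median of 2.19.

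**Figure D2:**
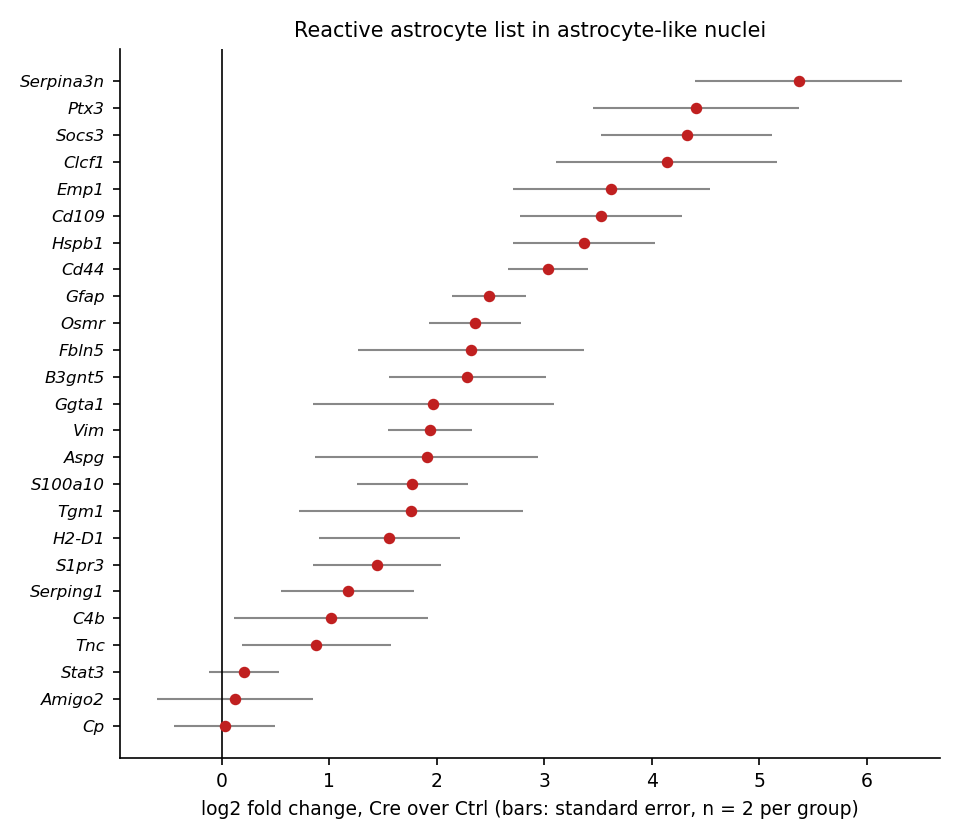
Log2 fold change of Cre over Ctrl (horizontal axis) for each tested member of the reactive astrocyte list (vertical axis) in astrocyte-like nuclei, with standard errors and n = 2 libraries per group. All 25 members lie above 0, from 0.03 for Cp to 3.04 for Cd44 and beyond.

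Genes of normal astrocyte function did not shift as a group. The astrocyte transport and homeostasis list had a median log2 fold of -0.08 in astrocyte-like nuclei (camera adjusted p = 0.398). Within it, the water channel gene Aqp4 had a log2 fold of 1.23 (SE 0.44), the GABA transporter gene Slc6a11 one of -0.79 (SE 0.29) and Apoe one of 0.97 (SE 0.45), none of them called. At Leiden resolution 0.5 Aqp4 was among the leading genes of an astrocyte-like cluster with 96.95% of its nuclei from Cre 2. The coenzyme Q biosynthesis list, the pathway in which Hpdl acts, had a median of 0.17 (adjusted p = 0.636), with Coq6 at 0.99 (SE 0.65), Coq8b at 0.54 (SE 0.47), Pdss2 at -0.35 (SE 0.28) and Pdss1 at -0.32 (SE 0.27). The list of sodium and potassium channels was lower in astrocyte-like nuclei, with 3 of 27 members above 0, a median of -0.75 and a camera adjusted p of 1.9e-06 (adjusted p = 0.691 with an estimated correlation). None of its members was called adjusted over the list alone, and DESeq2 called 4. Kcnma1, a calcium-gated potassium channel, had a log2 fold of -1.50 (SE 0.30), from 1279 and 1448 to 425 and 540 CPM. Kcnt2 at -2.75 (SE 0.78), Kcnh7 at -2.73 (SE 0.78) and Scn1a at -2.37 (SE 0.63) are genes of neurons, and their levels in Ctrl 1 and Ctrl 2 were 45.1 against 223, 144 against 754 and 32.3 against 116 CPM. The list median differed by 1.2 between the Ctrl libraries, which is more than between the groups.

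Other lists called by camera in astrocyte-like nuclei were lower for glutamate receptors (median -0.57, adjusted p = 1.2e-05, and 0.252 with the trend on gene span removed), for GABA receptors and chloride transport (-0.62, 1.2e-05) and for mitochondrial genome transcripts (-0.30, 0.0123). They were higher for p53 targets and apoptosis (0.55, 0.0233), cell cycle (0.69, 0.0040), activated microglia (0.61, 0.0018) and immature neuron genes (1.17, 8.5e-04). The receptor lists differed between the Ctrl libraries by 0.56 and 0.77, and the immature neuron list stood at -0.18 in Mild and 2.01 in Severe. Ribosomal protein genes in this class stood at 0.29 in Mild and 2.19 in Severe, and at -0.22 between Ctrl 2 and Ctrl 1. Without Cre replicate 2 the p53 (adjusted p = 0.398), cell cycle (0.261) and immature neuron (0.733) calls ended, without Ctrl replicate 1 those for p53 (0.123) and immature neuron genes (0.199), and without Cre replicate 1 that for glutamate receptors (0.0869). Mitochondrial genome transcripts encode 13 subunits of the respiratory chain, and 2 of the 13 were above 0, with mt-Nd2 at -0.87 (SE 0.33), mt-Nd4 at -0.47 (SE 0.25), mt-Nd4l at -0.61 (SE 0.51) and mt-Atp6 at -0.29 (SE 0.25). These transcripts are made in mitochondria and are only carried along with nuclei, at library medians of 0.0845% to 0.167% of UMIs. The list therefore cannot tell a change in their expression from a change in what was carried along. That list was no longer called without Ctrl replicate 1 (adjusted p = 0.0816) or without Cre replicate 1 (adjusted p = 0.272). In all, camera called 11 of 29 lists in astrocyte-like nuclei, 7 higher and 4 lower.

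Microglia, the brain's resident macrophages, take on an activated state around damage. In microglia or macrophage-like nuclei all 20 tested members of the activated microglia list were higher in Cre, with a median log2 fold of 1.32 and a camera adjusted p of 9.2e-13. The median stood at 1.03 in Mild and 1.43 in Severe, against -0.62 between Ctrl 2 and Ctrl 1. Ribosomal protein genes in this class stood at 0.25, 2.03 and -0.45 in the same order. With 16 members the groups did not overlap, where chance gives 3.33, but none was called over all genes or adjusted over the list alone (lowest adjusted p = 0.0561). The call held without each library in turn (adjusted p from 1.3e-12 to 6.8e-07) and not with an estimated correlation (adjusted p = 0.579). Apoe, a lipid carrier that activated microglia make, had a log2 fold of 1.99 (SE 0.49), from 198 and 160 to 493 and 932 CPM. Ccl2, a chemokine that draws monocytes, went from 0 and 1 UMIs to 13 and 107, a ratio of 147 with a counting interval of 25.9 to 5862. The lipase gene Lpl had a log2 fold of 2.37 (SE 0.66) and the growth factor gene Csf1 one of 2.22 (SE 0.66). A single cluster held 85.9% of the microglia-like nuclei of Ctrl 1, 90.8% of Cre 1 and 79.2% of Cre 2, and another held 91.5% of those of Ctrl 2. The list was called in 10 of the 11 sums, subcortical neuron-like nuclei excepted (adjusted p = 0.130), so its rise was not limited to microglia-like nuclei, and Apoe and Fth1 in it are also expressed by other cells.

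Nuclear genes of oxidative phosphorylation, the process that the coenzyme Q pathway feeds, were higher in pooled nuclei and in each of the 10 classes by at least 1 of the 2 lists, and chiefly in the Severe library. In pooled nuclei 36 of 37 tested members of the complex I list were above 0 (median log2 fold 0.92, camera adjusted p = 9.1e-05) and 36 of 39 of the list of complexes II to V (1.03, 1.1e-04). The medians were -0.02 and -0.06 in Mild and 1.60 and 1.70 in Severe, against 0.30 and 0.17 between Ctrl 2 and Ctrl 1. In astrocyte-like nuclei the medians were 0.90 and 0.88 (adjusted p = 1.4e-05 and 2.4e-04), with 0.05 and -0.14 in Mild. None was called adjusted over the list alone or over all genes, and without Cre replicate 2 the pooled calls ended (adjusted p = 0.154 and 0.0763), as they did in astrocyte-like nuclei (0.903 and 0.171). The complex I call in pooled nuclei also ended without Ctrl replicate 1 (0.0593). Ndufa1, a short accessory subunit of complex I, had a log2 fold of 1.87 (SE 0.78) in pooled nuclei, from 4.64 and 2.84 to 4.32 and 22.9 CPM. Cox4i1, a subunit of cytochrome oxidase, had one of 1.36 (SE 0.50), from 43.5 and 38.0 to 51.0 and 158. Ribosomal protein genes, which are no part of the respiratory chain, moved the same way, with a median of 0.14 in Mild and 2.32 in Severe in pooled nuclei.

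In excitatory neuron-like nuclei the list of genes induced by electrical activity or injury had a median above the Ctrl mean in Severe and below it in Mild, and that of glutamate receptors one below it in both. In telencephalic excitatory neuron-like nuclei 23 of 28 activity-induced genes were above 0 (median 1.35, camera adjusted p = 0.0166, and 0.856 with an estimated correlation), with -0.30 in Mild and 2.03 in Severe. The call ended without Cre replicate 2 (adjusted p = 0.172) and without Ctrl replicate 1 (0.395), and none was called adjusted over the list alone, while DESeq2 called 5 as higher. Ribosomal protein genes moved with them, by 0.00 in Mild and 1.92 in Severe in this class. Scg2, a precursor of secreted neuropeptides, had a log2 fold of 3.51 (SE 0.97), from 4.21 and 4.52 to 8.92 and 90.7 CPM. Inhba, a subunit of activin, had one of 2.41 (SE 0.65), from 28.4 and 16.5 to 46.1 and 192 CPM, and the pentraxin gene Nptx2 one of 2.85 (SE 0.86), from 4.66 and 5.02 to 8.08 and 62.0, so these 3 lay above both Ctrl libraries in Mild too. Homer1 went the other way at -1.01 (SE 0.27), from 363 and 528 to 203 and 239 CPM. In the same class 3 of 29 glutamate receptor genes were above 0 (median -0.31, adjusted p = 2.8e-05, and 0.856 with an estimated correlation), with -0.33 in Mild, -0.34 in Severe and 0.12 between Ctrl 2 and Ctrl 1. Grm3 at -1.22 (SE 0.36), Gria3 at -0.89 (SE 0.28) and Homer2 at -0.73 (SE 0.23) were among the lower members, none of them called. Nuclei of this class in Cre 2 came mostly from 2 clusters (41.6% and 48.7%), which held no more than 0.244% of the class each in any other library, so the folds also compare different clusters. Inhba and Nptx2 were among the leading genes of the second of them.

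Receptor and channel genes span long stretches of the genome, and in excitatory neuron-like nuclei long genes as a whole were lower in Cre, with a median log2 fold of -0.36 in the longest of 20 equal groups of genes and 0.53 in the shortest. The glutamate receptor call ended once the trend of the test on gene span was removed (adjusted p = 0.160 in excitatory neuron-like and 0.202 in pooled nuclei), since the members moved little more than genes of like span. Their median was -0.31 with quartiles of -0.54 and -0.16 before, and -0.18 with quartiles of -0.25 and 0.08 relative to genes of like span. Sodium and potassium channels in excitatory neuron-like nuclei had a median of -0.38 (adjusted p = 5.0e-05), 16 of 28 members did not overlap with Cre lower, where chance gives 4.67, and the call stayed with the trend removed (adjusted p = 0.0127), while the median fell to -0.20 relative to genes of like span (quartiles -0.57 and -0.05). Kcnb2 at -0.95 (SE 0.23), Kcnt2 at -1.2 (SE 0.30), Kcnq5 at -0.91 (SE 0.24) and Kcnh7 at -1.01 (SE 0.32) led it. The reactive astrocyte list was also higher in excitatory neuron-like nuclei (23 of 24 above 0, median 1.16, adjusted p = 1.6e-06), with 9 members called adjusted over the list alone and 5 by DESeq2. Gfap reached 4.66 and 5.74 CPM there, from 0.716 and 1.16 in Ctrl, against 409 and 434 in astrocyte-like nuclei of the same Cre libraries. Cd44 went from 2.55 and 4.04 in Ctrl to 11.3 in Cre 1 and 38.7 in Cre 2, and Emp1, a membrane protein and a leading gene of the second cluster of Cre 2, from 0.358 and 0.317 to 0.694 and 17.2.

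In inhibitory interneuron-like nuclei 8 lists were called higher, among them that of the integrated stress response, a programme that cells start when amino acids run short or mitochondria fail. Of 27 tested members 26 were above 0, with a median of 0.85, a camera adjusted p of 6.0e-08, 0.39 in Mild and 1.13 in Severe. Ribosomal protein genes in this class stood at 0.26 in Mild and 2.05 in Severe. With 21 members the groups did not overlap with Cre higher, where chance gives 4.5. None was called over all genes or adjusted over the list alone (lowest adjusted p = 0.0518), the call held without each library in turn (adjusted p from 3.0e-11 to 0.00391) and not with an estimated correlation (adjusted p = 0.641). The mitochondrial folate enzyme gene Mthfd2 had a log2 fold of 1.78 (SE 0.47), from 5.30 and 5.84 to 12.6 and 25.4 CPM. Asns, asparagine synthetase, had one of 1.42 (SE 0.40), the arginine transporter gene Slc7a1 one of 1.14 (SE 0.31) and the hormone gene Stc2 one of 2.31 (SE 0.60). All interneuron-like nuclei of Cre 2 came from 1 cluster (100%), led by Adarb2 and Vip, whereas 68.0% of Ctrl 1, 64.3% of Ctrl 2 and 53.5% of Cre 1 lay in another, with Lhx6 among its leading genes, so the folds of this class also compare different kinds of interneuron. The list median was 0.57 in excitatory neuron-like nuclei (adjusted p = 0.0295, and 0.197 without Cre replicate 2 and 0.141 without Ctrl replicate 1), 0.41 in pooled nuclei (0.0287) and 0.13 in astrocyte-like nuclei (0.109).

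In interneuron-like nuclei 3 of 27 glutamate receptor genes were lower and called adjusted over the list alone, against 0 over all genes. Among them Grin3a had a log2 fold of -1.07 (SE 0.21) and Gria3 one of -1.11 (SE 0.23). The list median was -0.26 (camera adjusted p = 2.0e-04, and 0.276 with the span trend removed and 0.641 with an estimated correlation). Activity-induced genes had a median of 1.56 (adjusted p = 0.00188), 0.08 in Mild and 1.93 in Severe, led by Gadd45b at 3.30 (SE 0.87), Nptx2 at 2.56 (SE 0.74), Vgf at 1.90 (SE 0.57) and Btg2 at 1.78 (SE 0.51), and the call ended without Cre replicate 2 (adjusted p = 0.871) and without Ctrl replicate 1 (0.0805), as it did with an estimated correlation (0.693). In subcortical glutamatergic neuron-like nuclei the glutamate receptor list had a median of -0.16 (adjusted p = 0.0199, and 0.174 without Cre replicate 2), and 1 member was called adjusted over the list alone. That member, the NMDA receptor subunit gene Grin2c, had a log2 fold of -2.91 (SE 0.53), from 26.5 and 45.6 to 7.74 and 3.54 CPM. Of these subcortical nuclei 99.0% in Cre 2 came from a cluster of their own, so that fold also compares different clusters.

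In oligodendrocyte-like nuclei 5 of 23 cholesterol biosynthesis genes were above 0, with a median of -0.42 and a camera adjusted p of 7.3e-04 (0.914 with an estimated correlation), and this pathway supplies the membrane of myelin. The median stood at -0.93 in Mild and -0.07 in Severe, none was called adjusted over the list alone, and the call ended without Cre replicate 1 (adjusted p = 0.634) and without Ctrl replicate 1 (0.173). Hmgcs1, the first committed enzyme of the pathway, had a log2 fold of -1.21 (SE 0.40), from 445 and 396 to 111 and 250 CPM. Fdft1 stood at -0.65 (SE 0.29) and Mvd at -0.66 (SE 0.38). Myelin genes in oligodendrocyte-like nuclei were not called as a list (adjusted p = 0.78), with Cnp at 0.52 (SE 0.29), Ermn at 0.51 (SE 0.36), Pllp at 0.33 (SE 0.29) and the gap junction gene Gjb1 at 2.62 (SE 0.67). In pooled nuclei, where 4 of 24 myelin genes were above 0 (median -0.53, adjusted p = 9.5e-06), the myelin component gene Mobp had a log2 fold of -1.16 (SE 0.27), from 98.2 and 138 to 47.4 and 58.0 CPM. That list moved with the lower share of oligodendrocyte-like nuclei in both Cre libraries, and its call ended without Cre replicate 1 (adjusted p = 0.122). Ugt8a at -0.90 (SE 0.28) and Opalin at -1.40 (SE 0.52) went with it, and the iron carrier gene Trf against it at 0.76 (SE 0.31).

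Oligodendrocyte precursor-like nuclei had higher antioxidant and metallothionein genes, with a median of 0.66 and a camera adjusted p of 1.5e-04 that became 0.0916 without Ctrl replicate 1 and 0.622 with an estimated correlation. Relative to genes of like span the median was 0.27 (quartiles -0.14 and 0.69), and ribosomal protein genes stood at 0.42 in Mild and 2.27 in Severe in this class. Adjusted over the list alone 1 of 17 members was called, and 0 over all genes. That member, the metal-binding Mt1, had a log2 fold of 1.38 (SE 0.32), from 17.9 and 20.9 to 50.7 and 50.9 CPM. Txnip stood at 1.66 (SE 0.47), Prdx1 at 1.00 (SE 0.33) and Sqstm1 at 1.04 (SE 0.36). All 37 complex I genes were above 0 in these nuclei (median 0.98, adjusted p = 1.8e-07), led by Ndufb11 at 2.00 (SE 0.54), Ndufb9 at 1.56 (SE 0.51), Ndufc2 at 1.74 (SE 0.58) and Ndufa8 at 1.72 (SE 0.58), with 0.08 in Mild, 1.52 in Severe and an adjusted p of 0.497 without Cre replicate 2. Precursor-like nuclei of Cre 2 lay almost all in a cluster of their own (99.3%).

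Cells of vessels and meninges, which arise outside the neural lineage for the most part, had higher medians of an oxidative phosphorylation list, together with ribosomal protein genes. The list of complexes II to V had a median of 0.90 in endothelial cell-like (camera adjusted p = 4.1e-10), 1.07 in mural cell-like (6.5e-07) and 1.19 in fibroblast or meningeal cell-like nuclei (3.0e-10). The medians were 0.21, 0.67 and 0.27 in Mild and 1.28, 1.41 and 1.64 in Severe, and the adjusted p were 0.145, 0.189 and 0.164 without Cre replicate 2 and 0.722, 0.819 and 0.663 with an estimated correlation. Ribosomal protein genes stood at 0.73, 1.24 and 0.66 in Mild and 1.74, 1.98 and 2.28 in Severe in the same 3 classes. Relative to genes of like span the list medians fell to 0.33 in endothelial cell-like, 0.16 in mural cell-like (quartiles -0.04 and 0.84) and 0.63 in fibroblast-like nuclei. The leading members of the list were Cox8a at 1.66 (SE 0.51), Cox4i1 at 1.60 (SE 0.50), Cox7c at 1.38 (SE 0.45) and Cox5a at 1.23 (SE 0.42) in endothelial cell-like nuclei, and Cox4i1 at 1.87 (SE 0.54) in fibroblast-like nuclei. In mural cell-like nuclei 1 of 15 members was called adjusted over the list alone, the ATP synthase gene Atp5l at 2.47 (SE 0.55). Endothelial cell-like nuclei also had higher antioxidant and metallothionein genes (median 0.61, adjusted p = 0.00495, and 0.0560 to 0.0826 without any 1 library, with a median of 0.21 and quartiles of -0.23 and 0.49 relative to genes of like span), led by the autophagy receptor gene Sqstm1 at 1.74 (SE 0.40), from 33.2 and 32.7 to 124 and 98.5 CPM. In fibroblast-like nuclei the activated microglia list had a median of 1.15 (adjusted p = 2.4e-04, and 0.0520 without Cre replicate 2), and the ferritin gene Fth1, at 1.43 (SE 0.30), was the 1 of 12 members called adjusted over the list alone.

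In pooled nuclei 16 of 32 lists were called by camera, 11 higher and 5 lower. Reactive astrocyte genes had a median of 1.25 (adjusted p = 4.3e-11), 1.11 in Mild and 1.31 in Severe, with 9 of 37 called adjusted over the list alone against 0 over all genes. Gfap there had a log2 fold of 2.71 (SE 0.32), from 5.31 and 5.33 to 35.1 and 34.8 CPM, Serpina3n one of 2.84 (SE 0.62), Hspb1 one of 2.24 (SE 0.53) and Cd44 one of 2.01 (SE 0.49). Activated microglia genes had a median of 0.96 (2.9e-09) with 6 of 26 called adjusted over the list alone, among them the osteopontin gene Spp1 at 2.76 (SE 0.62), the chemokine gene Ccl3 at 4.27 (SE 0.98), Apoe at 1.38 (SE 0.34) and Ccl2 with a ratio of 79.9 and a counting interval of 27.0 to 390. Immature neuron genes (0.98, adjusted p = 0.00171, 0.10 in Mild), with Igfbpl1 at 2.36 (SE 0.75), and cell cycle genes (1.16, 5.4e-06, 0.12 in Mild), with Cdk1 at 2.45 (SE 0.95), were not called without Cre replicate 2 (0.887 and 0.803). Glutamate receptors had a median of -0.43 (1.6e-06), with Gria3 at -1.10 (SE 0.33), Grm7 at -0.96 (SE 0.29), Grin3a at -0.70 (SE 0.22) and Grik1 at -0.72 (SE 0.25). GABA receptors and chloride transport (-0.53, 4.2e-05), sodium and potassium channels (-0.32, 5.4e-06) and mature neuron genes (-0.24, 0.0176) were lower too, beside mean shares of 26.3% in Ctrl and 13.7% in Cre for excitatory neuron-like and 5.70% and 2.61% for interneuron-like nuclei. Integrated stress response (0.41, 0.0287), p53 targets and apoptosis (0.42, 0.0276), antioxidant and metallothionein (0.45, 0.0101) and cytosolic heat shock genes (0.89, 0.0415) were higher. These last 4 calls ended without Cre replicate 2 (adjusted p from 0.466 to 0.486) and without Ctrl replicate 1 (0.251 to 0.647), and that for mature neuron genes without Cre replicate 1 (0.898) and without Ctrl replicate 2 (0.303).

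Choroid plexus genes were the remaining list called in pooled nuclei (median 0.56, camera adjusted p = 0.0155, and 0.358 without Cre replicate 1 and 0.0570 without Ctrl replicate 1), and 1 of its 10 members was called adjusted over the list alone. The list was set as a check for contamination by choroid plexus RNA. Ttr, the thyroid hormone carrier that choroid plexus epithelium secretes, had a log2 fold of 3.31 (SE 0.40), from 5.53 and 8.29 to 51.1 and 86.4 CPM, and DESeq2 called it (adjusted p = 8.5e-08). It was higher by 2.62 to 3.68 log2 units in each of 9 classes, and in mural cell-like nuclei it went from 0 and 1 UMIs to 13 and 39, a ratio of CPM of 38.2 with a counting interval of 6.56 to 1537. The rise was thus not particular to any class, and free choroid plexus RNA cannot be told apart here from expression in these nuclei. Folr1 stood at 1.66 (SE 0.53), Slc4a5 at 1.2 (SE 0.55) and Cldn2 at 1.66 (SE 0.88). Choroid plexus epithelium-like nuclei made up 0.0131% and 0.209% of Ctrl and 0.554% and 0.198% of Cre. The lists not called in pooled nuclei had medians of 0.04 for coenzyme Q biosynthesis (adjusted p = 0.811), -0.09 for mitochondrial genome transcripts (0.164), 0.06 for mitochondrial chaperones and proteases (0.80), 0.09 for glycolysis and lactate (0.923), 0.12 for fatty acid oxidation and ketone bodies (0.765), -0.01 for cholesterol biosynthesis (0.163), 0.12 for astrocyte transport and homeostasis (0.627) and 0.97 for activity-induced genes (0.0809). They were -0.05 for interferon response (0.638), 0.02 for hypoxia response (0.938), 0.41 for endoplasmic reticulum stress (0.149), 0.60 for glucocorticoid response (0.163), -0.28 for circadian clock (0.105), 0.02 for tyrosine and catecholamine metabolism (0.938), -0.21 for erythroid (0.685) and -0.26 for sex-linked transcripts (0.167). For coenzyme Q, chaperones and glycolysis the test pointed down against a median above 0, and for cholesterol the mean was 0.00.

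**Figure D3:**
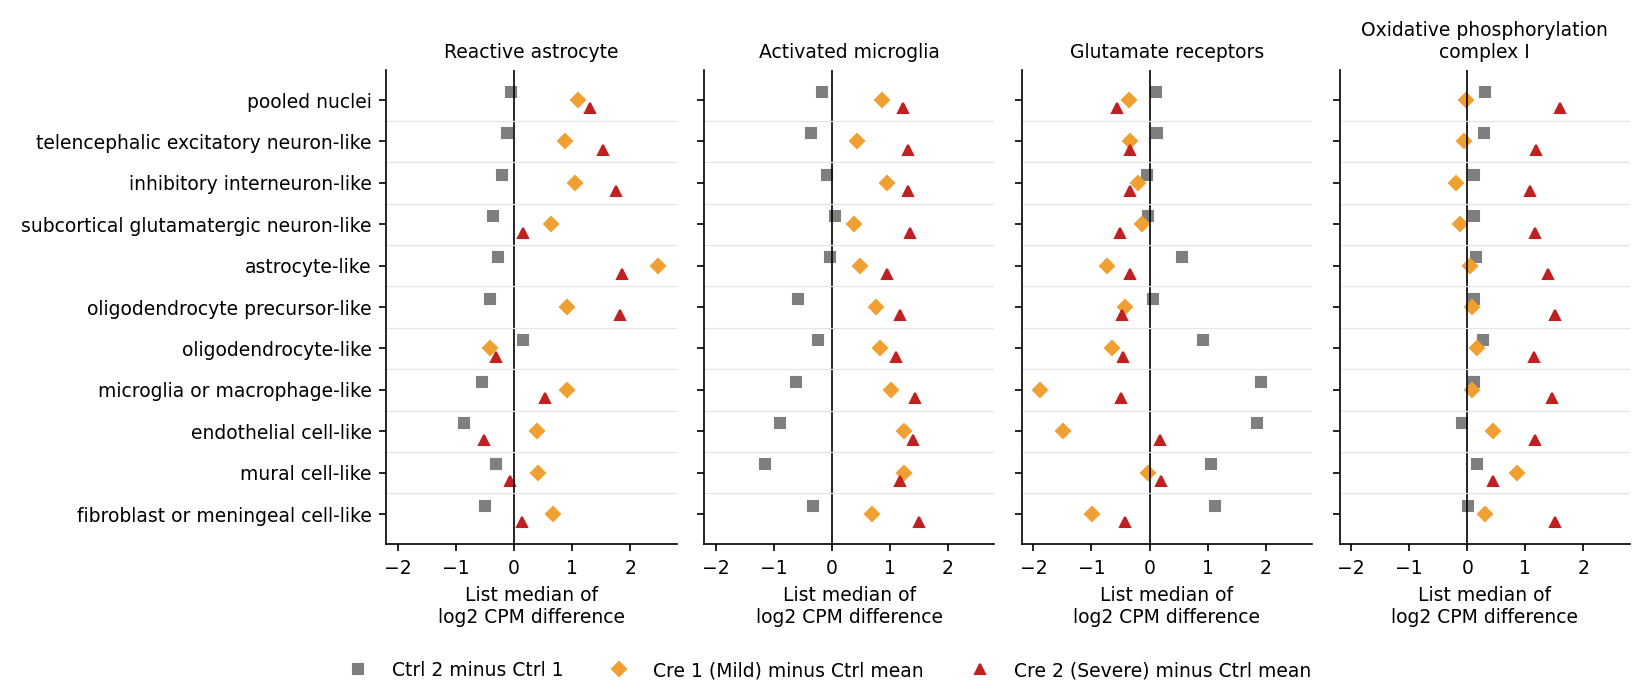
Median over the members of a gene list of the difference in log2 CPM (horizontal axis), for the pooled nuclei and each class (vertical axis), of each Cre library against the Ctrl mean and of Ctrl 2 against Ctrl 1. In astrocyte-like nuclei the reactive astrocyte list lies at 2.48 in Mild and 1.85 in Severe, and complex I in pooled nuclei at -0.02 in Mild and 1.60 in Severe.

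Across the 10 classes and pooled nuclei camera called 4 to 16 lists, namely 16 in excitatory neuron-like, 14 in interneuron-like, 4 in subcortical neuron-like, 11 in astrocyte-like, 14 in precursor-like, 8 in oligodendrocyte-like, 16 in microglia-like, 12 in endothelial-like, 4 in mural-like and 14 in fibroblast-like nuclei. With an estimated correlation and with fry for a shift one way 0 were called in each of the 11. Fry for change in either direction called the reactive astrocyte list in astrocyte-like and pooled nuclei and the choroid plexus list in pooled nuclei (adjusted p = 0.0455 for both in pooled nuclei). In 36 of the 304 list tests the median, the mean and the direction of the test differed in sign, none of them called. Neither fry test compares a list with other genes, whereas camera does.

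Whether astrocytes and neurons differed in their response was tested directly between astrocyte-like and excitatory neuron-like nuclei. Of 19027 genes edgeR called 0, with 961 at an unadjusted p under 0.05 and a lowest adjusted p of 0.938, and DESeq2 was not run for this contrast. In simulated data this test called 2 of 100 genes changed 2-fold in astrocyte-like nuclei alone and 24 of 100 changed 4-fold. Reactive astrocyte genes had a median difference of 0.46 log2 units in favour of astrocyte-like nuclei, with 25 of 32 above 0 and 1 called adjusted over the list alone. That gene, the surface protein gene Cd109, differed by 2.86 (SE 0.48). Gfap differed by 0.20 (SE 0.50), Cd44 by 0.44 (SE 0.52) and Vim by -0.06 (SE 0.50), so for these markers no difference in fold between the classes was seen. The level of Gfap was far lower in excitatory neuron-like than in astrocyte-like nuclei, as given above. Free RNA from astrocytes would give a like fold in both classes, so this test cannot tell it from a response of neurons. Activity-induced genes differed by a median of -0.50, with 3 of 28 called adjusted over the list alone. Without Cre replicate 1 the test called 144 genes, 52 of them higher in astrocyte-like nuclei.

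The Severe and the Mild library were set side by side without a test, since each is a single library, so this compares those libraries and not the conditions. Genes were counted that differed by more than 1 log2 unit and by more than 2 times the log2 ratio between the Ctrl libraries. In pooled nuclei 685 of 6718 genes passed both limits, 387 higher in Severe and 298 higher in Mild. Between the Ctrl libraries 200 genes differed by more than 1 log2 unit, a count without the second limit and so not of the same kind. With equal class shares 436 genes passed both limits, 310 higher in Severe and 126 higher in Mild. That setting kept only the 10 tested classes, gave each the same weight in every library and used CPM without TMM factors. Clusters within a class stayed unequal, so the counts of the 2 settings differ by more than class shares. Highest in Severe were Gm42912 at 7.37, Gm2694 at 4.22, Il16 at 4.05, Gm29521 at 3.89 and Ebf3 at 3.57, of which Gm42912, Gm2694 and Il16 were among the leading genes of a granule-like cluster with 99.4% of its nuclei from Cre 2, and lowest were Pcsk2os2 at -3.11, Gm10754 at -3.02, Gm17171 at -2.99, Gm15813 and Dlx6os1. In astrocyte-like nuclei 743 of 6989 genes passed both limits, 382 of them higher in Severe. Between the Ctrl libraries 708 differed by more than 1 log2 unit there, again without the second limit. There Mybpc1 stood at 7.71, Pax3 at 6.12, the retinoic acid-degrading Cyp26b1 at 5.72, Gria4 at 5.03 and Stk32a at 4.52, and at the other end Otc at -3.94, Hapln1 at -4.09, Gm20528 at -4.69, Gm13110 and Thbs4, a secreted protein of forebrain astrocytes, at -6.18. The reactive astrocyte list differed by -0.02 in astrocyte-like nuclei, at percentile 45.3 of 10000 random lists of like expression, and cholesterol biosynthesis by 0.98 (percentile 100). In pooled nuclei the reactive astrocyte list was higher in Severe, by 0.22 (percentile 91.8). With equal class shares it differed by 0.50 (percentile 98.1), above the central 95% of random lists (-0.15 to 0.48). The interferon response list was higher in Mild, by -0.94 in astrocyte-like (percentile 0.42) and -0.74 in pooled nuclei (percentile 1.38), where equal class shares left -0.12 (percentile 10.5), inside the central 95% of random lists (-0.30 to 0.59). The 2 oxidative phosphorylation lists differed by 1.62 and 1.70 in pooled nuclei, cell cycle by 1.66 and immature neuron genes by 1.54 (percentile 100 each), and with equal class shares by 1.56, 1.55, 1.08 and 1.22 (percentile 100 each). Ctrl 2 against Ctrl 1 gave 0.30, 0.17, 0.13 and 0.11 in pooled nuclei (percentiles 99.95, 96.2, 93.05 and 61.7). With equal class shares these Ctrl percentiles were 100, 99.8, 63.2 and 51.3, and 17 for the reactive astrocyte list. A percentile thus sets a list against other genes within a single pair of libraries and does not measure the spread between mice.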

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

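The tests of other tissue, of the Severe phenotype, of cytosolic RNA, of the shared genotype and of another brain region were chosen only after the results they measure were seen, as was that of gene span within single classes, and those of gene span in pooled nuclei and of free RNA before.

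3 unnamed clusters that enter no comparison of a class held more nuclei in a Cre library than in either Ctrl library. A cluster with Dlx6os1, Dlx6, Dlx1, Dlx2 and Meis2, genes of young inhibitory neurons, among its leading genes held 8.82% of Cre 1 (876 nuclei, exact 95% interval 8.27 to 9.40) against 3.89% and 2.93% of Ctrl 1 and Ctrl 2, and 0.198% of Cre 2. A cluster led by Atp6v0c, Sst, Actb and Tmsb10 held 7.79% of Cre 2 (1296 nuclei, interval 7.39 to 8.21) against 0.0261% and 0.00615% of Ctrl, with a median of 709 UMIs per nucleus and the ribosomal protein genes Rps3 and Rpl18 among its leading genes. A cluster led by Pax2, Tfap2a, Slc6a5, Tfap2b and Kit, genes of inhibitory neurons of cerebellum and hindbrain, held 6.32% of Cre 2 (1052 nuclei, interval 5.96 to 6.71) against 0 nuclei in both Ctrl libraries.

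Cerebellar granule neuron-like and Purkinje neuron-like nuclei lay nearly all in the Severe library. If other tissue had been taken for it, its glia would carry the code of the other region, and in oligodendrocyte precursor-like nuclei 15 hindbrain and midbrain code genes such as the Hox genes summed to 4.76 times the highest other library (66.5 against 13.9 CPM). The ratio was 8.22 in microglia-like nuclei, which share RNA with their surroundings but do not carry this code, and the 5 telencephalic code genes in precursor-like nuclei stood at 0.757 of the lowest other library, while in astrocyte-like nuclei the 2 codes stood at 5.02 times the highest and 0.312 of the lowest other library. So a larger share of hindbrain tissue may explain the pattern in part, with free RNA in the same counts. The Ctrl mice, which are not described as Severe, gave granule-like nuclei at only 0.0261% and 0.00615% and 0 Purkinje-like nuclei. Their libraries thus held almost no cerebellum, which argues against the Severe phenotype as the source of these nuclei. Whether the phenotype changed other shares of the Severe library stays open, since 1 library came from an animal with that description. There it and a difference in tissue cannot be told apart.

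Nuclear genes of oxidative phosphorylation were higher in every class by at least 1 list, a pattern that is in short, well-expressed genes. Gene span and expression as the whole cause were argued against, since the members' median log2 fold of 0.98 in pooled nuclei lay at percentile 100 of 10000 lists matched on both, 0.65 above their median of 0.33, and in 9 of 10 classes (percentile at least 99.97, with 0.33 to 0.70 above), though removal of the trend on span ended or weakened the pooled call (adjusted p = 0.0351 for complex I and 0.0640 for complexes II to V) and span stays open in mural cell-like nuclei (percentile 97.6, under the limit of 99.75 for 10 classes, which replaced a lower limit that this value passed, after it was seen). The shared genotype was argued against for pooled nuclei, where the Mild library stood at -0.0562 against the Ctrl mean. Cytosolic RNA carried along with the nuclei of the Severe library is a candidate explanation, since ribosomal protein genes there were raised by a median of at least 1.74 log2 units in each of the 10 classes. A response of mitochondria in the Severe mouse stays open beside it, as no library of a further Severe mouse was at hand.

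The reactive astrocyte list was higher in astrocyte-like nuclei of both Cre libraries. Another brain region in the Severe library was argued against as the whole cause, since Cre 1 against Ctrl 1, whose astrocyte-like nuclei share a cluster, gave a list median of 2.19. Cytosolic RNA in the Severe library was argued against in the same way by the Mild library's median of 2.48. Free RNA from other cells was argued against by the rise per member in astrocyte-like nuclei, which exceeded that in precursor-like nuclei by a median of 1.83 log2 units in the lower of the Cre libraries and 2.00 in the other. A reaction of astrocytes to the loss of Hpdl from neural cells may therefore underlie it, as a hypothesis found and tested on the same data, and an effect of the Nestin-cre transgene itself stays open, since no library carried it without the floxed allele.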

How the results depend on the processing

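The doublet limit of 0.25, the shares outside the cerebellar and cycling classes, the pooled nuclei of the 10 classes and the removal of the gene span trend were chosen after seeing the data. Of the counts for whole comparisons 182 stayed within 1.5 times of the reported count and 87 did not, and the latter follow. Among 148 results for named genes, 1758 of 1761 values kept their sign, 3 turned, none of them called, and 168 passed the threshold in an alternative. Of 129 called lists 24 turned direction when a library was left out, 21 of them only without Cre replicate 2 and 3 without Ctrl replicate 2 and without Cre replicate 1, none past the threshold there. Outside the cerebellar and cycling classes the mean share in Cre went from below to above the Ctrl mean for mural cell-like (0.767% against 0.707%), fibroblast-like (3.72% against 3.21%) and precursor-like nuclei (6.88% against 5.96%), since the nuclei removed were nearly all of Cre 2.

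RLE factors, doublets kept, 1 doublet limit, at least 1000 UMIs, thinning and the pooled nuclei of the 10 classes left the edgeR counts of called genes at 0, as reported, in every sum where each was run. With no filter on low counts edgeR called 1 gene in pooled nuclei, 85 in excitatory neuron-like, 447 in interneuron-like, 375 in subcortical neuron-like, 536 in astrocyte-like, 359 in precursor-like, 184 in oligodendrocyte-like, 244 in microglia-like, 38 in endothelial-like, 13 in mural-like and 274 in fibroblast-like nuclei. DESeq2 called 43, 130, 33, 26, 97, 31, 14 and 19 genes in the first 8 of these sums, 1 in mural-like and 0 in endothelial-like and fibroblast-like nuclei. For both alternatives the cause was not tested.

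Leaving out single libraries moved the gene counts from 0 to 2554 in pooled nuclei, 0 to 2047 in excitatory neuron-like, 0 to 1072 in interneuron-like, 0 to 2659 in subcortical neuron-like, 0 to 197 in astrocyte-like, 0 to 383 in precursor-like, 0 to 1 in oligodendrocyte-like, 0 to 124 in microglia-like, 0 to 134 in mural-like and 0 to 76 in fibroblast-like nuclei. The highest counts came without Cre replicate 1, except in microglia-like nuclei, where they came without Ctrl replicate 1 (which also gave 15 genes in precursor-like and 8 in mural-like nuclei), and in oligodendrocyte-like nuclei, where the 1 gene came without Cre replicate 2. Without Cre replicate 2 the counts were 7 in pooled, 19 in excitatory neuron-like, 9 in subcortical neuron-like and 8 in mural-like nuclei. In these fits the lone Cre library is assumed to vary like the Ctrl pair, so the high counts set the Severe library against the spread between controls. Without Cre replicate 1 the share test called 3 classes of nuclei (0 to 3 over the libraries) and the interaction test 144 genes (0 to 144).

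With the replicate number as a block, which assumes that mice of like number are paired, edgeR called 20 genes in interneuron-like, 1 in astrocyte-like, 1 in precursor-like, 3 in microglia-like and 285 in fibroblast-like nuclei, and 2 classes of nuclei, with the lowest adjusted p at 0.0143 for immature or cycling neural cell-like nuclei. The labels do not say that the numbers pair the mice. The replicate block gave no value for Hpdl, which lay below the filter.

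Lists called by camera fell to 0 in each of the 11 sums with an estimated correlation and with fry, for which the cause was not tested. With the gene span trend removed 10 lists were called in pooled, 8 in excitatory neuron-like, 0 in subcortical neuron-like, 3 in endothelial-like, 1 in mural-like and 5 in fibroblast-like nuclei. In pooled nuclei the glutamate receptor call ended because long genes as a whole were lower (median log2 fold -0.38 in the longest of 20 groups, 0.48 in the shortest): its median was -0.43 (quartiles -0.62 and -0.18) before and -0.21 (-0.38 and 0.13) relative to genes of like span. The list of complexes II to V went from 1.04 (0.78 and 1.32) to 0.63 (0.37 and 0.86) and lost its call. Leaving out single libraries gave 10 to 19 lists in pooled, 10 to 15 in excitatory neuron-like, 1 to 8 in subcortical neuron-like, 9 to 15 in precursor-like, 8 to 16 in microglia-like, 5 to 12 in endothelial-like, 0 to 9 in mural-like and 7 to 13 in fibroblast-like nuclei. The lowest counts came without Cre replicate 2 in pooled, excitatory neuron-like, subcortical neuron-like, microglia-like, mural-like and fibroblast-like nuclei, without Ctrl replicate 1 in precursor-like and without Ctrl replicate 2 in endothelial-like nuclei.

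Severe against Mild with equal class shares left 436 genes over 1 log2 unit and over 2 times the Ctrl ratio in pooled nuclei, against 685, with 310 against 387 higher in Severe and 126 against 298 higher in Mild, and the cause was not tested. That setting also left out the nuclei outside the 10 tested classes, and the TMM factors. Depth limited Hpdl, with 0 to 2 UMIs per library in every setting run, and the classes with few nuclei.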

Other observations

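The genes in this part were chosen after their values were seen.

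Genes outside the fixed lists with low p in astrocyte-like nuclei were Morrbid, Hpgd and Itga5. Morrbid, a long non-coding RNA that keeps myeloid cells alive, had a log2 fold of 4.96 (SE 0.44), from 1.60 and 1.27 CPM in Ctrl to 41.5 and 47.1 in Cre (edgeR adjusted p = 0.438, DESeq2 adjusted p = 4.4e-09). Hpgd, the enzyme that inactivates prostaglandin E2, had a log2 fold of 4.03 (SE 0.51), from 11.6 and 4.87 to 106 and 154 CPM (edgeR adjusted p = 0.851, DESeq2 adjusted p = 1.6e-09). Itga5, the fibronectin receptor subunit, had one of 2.87 (SE 0.47), from 7.18 and 4.44 to 31.3 and 52.0 (DESeq2 adjusted p = 0.00133). In oligodendrocyte precursor-like nuclei the chromatin protein gene Hmga2 had a log2 fold of 1.84 (SE 0.36), from 17.2 and 29.7 to 97.0 and 73.2 CPM (DESeq2 adjusted p = 0.0271), and the intermediate filament gene Vim one of 2.96 (SE 0.60). None of these was called by edgeR over all genes.

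In microglia or macrophage-like nuclei the chemokine gene Ccl12 had a log2 fold of 3.87 (SE 0.83), from 3.57 and 7.73 to 38.5 and 142 CPM, and the inhibitory receptor gene Cd300lf one of 2.60 (SE 0.56). Hmox1, the haem-degrading enzyme, went from 1 and 2 UMIs to 18 and 18, a ratio of 14.7 with a counting interval of 4.65 to 74.7, and Cxcl16 from 1 and 1 to 17 and 16, a ratio of 20.2 with an interval of 5.18 to 174. In pooled nuclei the long non-coding RNAs Neat1 and E130114P18Rik had log2 folds of 1.46 (SE 0.27) and 1.84 (SE 0.30), and Ccl12 one of 3.74 (SE 0.77), with DESeq2 adjusted p of 0.113, 0.0245 and 0.00422. None of these was called by edgeR over all genes.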
